A study of Arabidopsis thaliana with 10 samples.

How the data were processed

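The series holds 10 libraries from whole seedlings of Arabidopsis thaliana ecotype Ler at 5 days: 3 RNA libraries each of WT (E5-4) and homozygous fve-8, and 2 small RNA libraries each of the same genotypes. Per the labels' protocols, seedlings grew on MS medium without treatment, RNA was extracted with Trizol, and RNA libraries were made with the TruSeq Stranded Total RNA kit. Total RNA libraries of this kind keep plastid and non-coding transcripts, so that plastid genes hold a large part of the counts. Per the submitters' processing notes, the tools used were TopHat2, SAMtools, HTSeq and edgeR; versions, the genome build and the counting mode for strand and for reads with several positions are not given in the sources used here. Reads from overlapping or antisense features and from near-identical copies may therefore be counted on either or on neither.

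The authors deposited 1 table per assay, each with whole-number read counts per feature and library, not normalized. The RNA table covers 73194 features, 28496 of them nuclear genes, with plastid, mitochondrial and non-coding loci and 31189 transposable elements, and the small RNA table covers 428 mature miRNA entries, from RNA of 19 to 24 nt per the labels. The deposited tables also hold the authors' own log2 fold changes and p-values with adjusted p-values, which were not used for any test here, and each sentence that prints a value from them names the authors' deposited table. Per the file headers, the RNA table carries the column names of a DESeq2 output and the small RNA table those of an edgeR output. Gene names were taken from the RefSeq table of the TAIR10.1 assembly, which matched 28009 of the 28496 nuclear gene identifiers; it was used for names and for which genes neighbour each other, and no coordinates are given because the authors' build is not given in the sources used here. It holds 0 of the 428 miRNA identifiers and no transposable elements.

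Library totals were 16161800 to 19599058 counts for RNA and 376797 to 1280675 for small RNA, where both WT libraries held more counts than both fve-8 libraries. The small RNA totals cover mature miRNA entries only, so they do not tell sequencing depth from the miRNA part of the reads. A count of 0 allows up to 3 counts, or 0.153 to 0.186 CPM in the RNA libraries and 2.34 to 7.96 CPM in the small RNA libraries; floors and intervals cover counting error only. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of 2.78 to 4.31 between WT RNA libraries, 18.4 to 46.4 between fve-8 RNA libraries, and 34.9 and 25.2 between the small RNA pairs of WT and fve-8, so each library was counted as its own sample.

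Each assay was fitted alone with genotype as the only term, using edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM normalization, the quasi-likelihood test and Benjamini-Hochberg adjustment, with a call at an adjusted p under 0.05. The filter left 19543 RNA features, of which 19086 were genes, and 271 small RNA entries. CPM values use TMM-scaled library sizes, the SE of a log2 fold change was taken from the fold change and its F statistic, and SDs are over the libraries of a genotype. Class enrichments used Fisher's exact test over the tested features, adjusted over 5 classes, and shares of counts an exact permutation test.

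Before the data were examined, 24 gene lists were fixed for the pathways, stress responses and tissue markers that fit the genotype and seedling tissue. Of 377 listed members 12 were left out because the reference does not give the listed symbol at that locus. Lists with at least 3 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists, and no list kept its call with an estimated correlation. The named genes followed a rule fixed at the same time: any member of the autonomous pathway, FLC, silencing machinery and TAS lists, the 4 called members with the largest change of any other list, and the 12 higher and 12 lower genes with the largest change among called genes with a mean of at least 2 CPM and no overlap between genotypes. For small RNAs, elements and plastid genes, whose identifiers have no names here, at most 2 identifiers per direction are printed. Further called members of the lists stand in the counts only.

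The tests were checked on simulated counts with known changes. At RNA depth, 22.4%, 74.6% and 98.5% of genes changed 1.5-fold, 2-fold and 4-fold were recovered, with 8 false calls among 19279 features. For small RNA 7.14%, 38.5% and 84.6% were recovered, with 0 false calls among 261. Features were simulated independently and with the same spread in both genotypes, whereas the fve-8 RNA libraries differed more than the WT ones. The recovered shares and false calls may therefore not hold for these data. The alternatives tried were another normalization, library totals only, other count filters, DESeq2 1.42.0, the likelihood-ratio test, limma-voom, the replicate number as a block, a fold threshold, leaving out each library, and, chosen after seeing the data, leaving out organelle genes, collapsing near-identical small RNA entries and thinning the small RNA libraries to the smallest. A planned comparison of miRNA families with their targets was not run, because the miRNA identifiers could not be paired with families, and for the same reason the planned single miRNAs are not named.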

Results

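Whole seedlings of Arabidopsis thaliana, ecotype Ler, were profiled at 5 days of age in a homozygous fve-8 mutant and in E5-4, the line the labels give as its wild type and which is called WT here. FVE encodes a WD40-repeat protein that works with histone deacetylases and is best known as a repressor of the floral repressor gene FLC in the autonomous flowering pathway. The series title places FVE beside SGS3, DRB4 and DCL4, components of the pathway that makes small interfering RNAs against transgenes. RNA was sequenced from 3 libraries per genotype, with 16161800 to 19599058 counts per library over 73194 features. Small RNA was sequenced from 2 libraries per genotype, with 376797 to 1280675 counts over 428 mature miRNA entries. The labels number the replicates without saying that they came from separate cultures, so p-values of the fits here measure the spread between these samples, which may be technical. P-values of Fisher's exact test over features do not measure that spread.

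The first comparison asked which transcripts differed between fve-8 and WT seedlings. FVE itself (AT2G19520) stood at 9.97, 8.67 and 9.0 CPM (counts scaled to the effective library size) in WT replicates 1 to 3 and at 6.61, 5.63 and 5.40 in fve-8, a log2 fold change of -0.65 ± 0.14 (SE, adjusted p = 0.0184). Of 8 seed storage and late embryogenesis genes 6 fell in fve-8, as did the 3 cold-response CBF genes, while 3 of 4 jasmonate, 5 of 9 iron-deficiency and 8 of 18 glucosinolate genes rose. The jasmonate, iron-deficiency and glucosinolate lists were called with a preset correlation, and each had an adjusted p = 0.213 with an estimated correlation, against 0.295 for the seed and 0.366 for the cold list. Among transposable elements 80 rose and 9 fell. Of 19086 tested genes, 1200 were higher and 976 lower in fve-8 with edgeR's quasi-likelihood test at an adjusted p under 0.05, of which 364 and 116 differed at least 2-fold. Single libraries moved the counts, as 291 of these calls remained without WT replicate 1, 307 without WT replicate 2, 662 without WT replicate 3 and 638 without fve-8 replicate 2. Without fve-8 replicate 3, 2311 genes were called higher and 1952 lower. On the first 2 principal components, which held 51.2% and 22.0% of the variance, the genotypes separated on the first, and fve-8 replicate 3 lay at 40.4 on the second against -27.2 for fve-8 replicate 1. The authors' deposited table lists 1110 genes higher and 783 lower at an adjusted p under 0.05, and 1729 of the 2176 genes called here were also called, with the same sign, in the authors' deposited table.

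Plastid transcripts took a smaller part of the fve-8 libraries. They made up 45.4% ± 0.534 of counts in WT (SD, n = 3) and 36.6% ± 3.14 in fve-8, while nuclear genes made up 52.7% ± 0.593 and 61.1% ± 3.65. Each difference had an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries can give. Of 95 tested plastid genes 31 fell, against 4.93% of the other features (Fisher's exact test, adjusted p = 9.7e-17), and 10 rose. That test takes genes as independent draws, and its p does not measure the spread between libraries. ATCG00690 went from 6907 ± 340 CPM to 3350 ± 280 (log2 fold change -1.04 ± 0.14), whereas ATCG00810 went from 90.5 ± 13.1 to 321 ± 104 (1.83 ± 0.23). The files do not pair these identifiers with names. Among 41 tested mitochondrial genes 10 fell. The scaling mattered here. With library totals alone the median log2 fold change of all features moved from -0.01 to 0.33, and 5440 genes were called higher and 181 lower. The changes below use TMM scaling and are relative to the median feature.

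Transposable elements were the class with the largest share of features called higher. Of 297 tested elements, 80 rose (26.9%, against 6.29% of the other features, Fisher's exact test, adjusted p = 1.3e-27) and 9 fell. That test takes elements as independent, although near-identical elements may share reads. The elements' share of unscaled library counts was 0.107% ± 0.00441 in WT and 0.162% ± 0.0243 in fve-8 (SD, n = 3, exact two-sided permutation p of 0.1, the smallest possible). This share also moves with the lower plastid share. With TMM scaling the rise was smaller, as the tested elements summed to 1080 ± 34.8 CPM in WT and 1261 ± 99.8 in fve-8. AT3TE68730 had 0 counts in the WT libraries and 5.97 ± 2.33 CPM in fve-8, at least 90.9-fold higher when 3 counts over the WT group are taken as the floor (adjusted p = 0.00108). AT1TE56400 had 2 counts in WT and 5.81 ± 2.2 CPM in fve-8, a ratio of 133 with a 95% counting interval of 36.7 to 1096. AT1TE39515 and AT1TE42395 fell, with log2 fold changes of -1.35 ± 0.21 and -1.12 ± 0.19, the latter not called without WT replicate 1 or 2. SDC (AT2G17690), an F-box gene kept silent by DNA methylation, was the only tested member of its list and rose from 0.194 ± 0.126 to 1.01 ± 0.421 CPM (2.30 ± 0.53, adjusted p = 0.0245). Of 22 tested genes of RNA-directed DNA methylation 1 rose, IDN2 (AT3G48670), with a log2 fold change of 1.65 ± 0.31. The list as a whole was not called (camera, adjusted p = 0.863). The call of SDC was lost without WT replicate 1, 2 or 3, and that of IDN2 without WT replicate 1, WT replicate 2 or fve-8 replicate 2. Without WT replicate 1, WT replicate 2 or fve-8 replicate 3 the elements called higher numbered 48, 51 and 121. Those called lower numbered 2, 2 and 14 there, 5 without WT replicate 3 and 4 without fve-8 replicate 2, and reads shared between near-identical elements could move counts from one element to another.

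**Figure D1:**
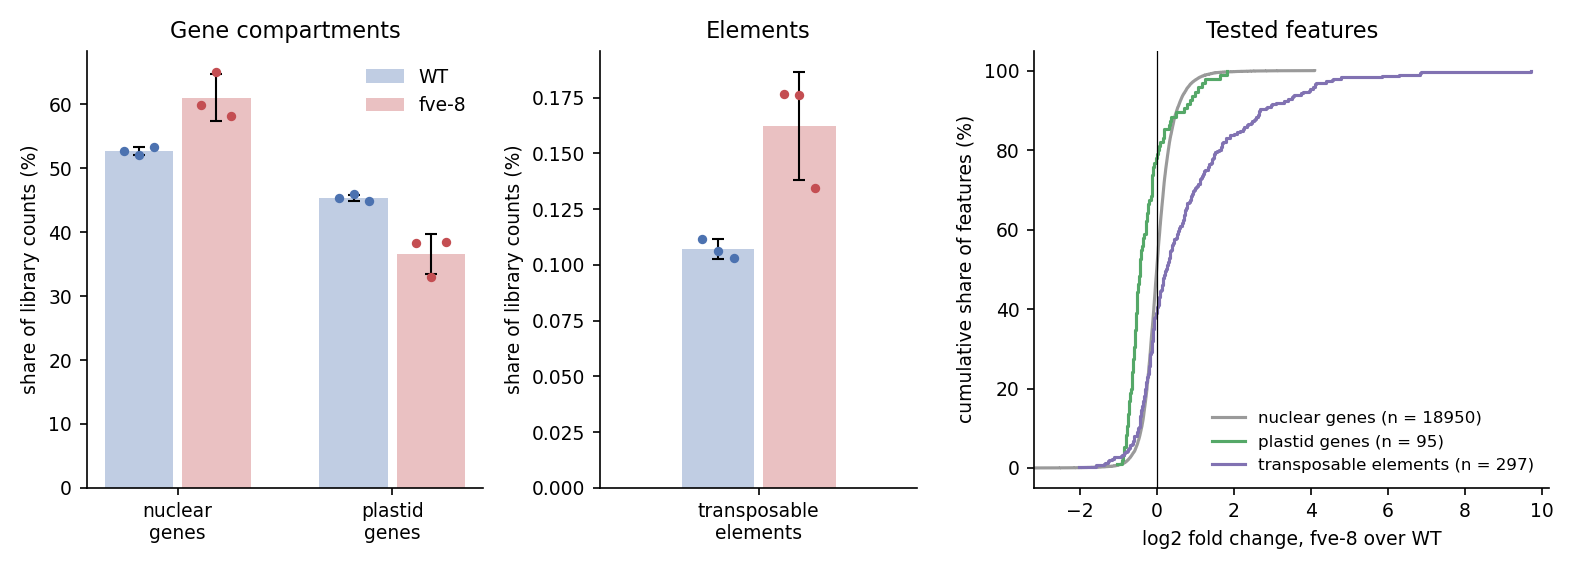
Left and middle, share of each RNA library's counts in percent for nuclear genes, plastid genes and transposable elements; bars are means, whiskers SD and points the 3 libraries of WT (blue) and fve-8 (red). Right, cumulative share in percent of tested features against the log2 fold change of fve-8 over WT; the curve of the 297 elements lies to the right of that of the 18950 nuclear genes above 0, and the curve of the 95 plastid genes to its left below 0.

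Genes of the silencing pathway named in the series title showed small differences. SGS3 (AT5G23570), which stabilises RNA for double-strand synthesis, had 20.0 ± 2.24 CPM in WT and 22.5 ± 3.44 in fve-8 (SD, n = 3; log2 fold change 0.17 ± 0.14), DRB4 (AT3G62800) 5.79 ± 0.713 and 6.26 ± 1.08 (0.12 ± 0.17), and DCL4 (AT5G20320) 12.3 ± 2.17 and 11.6 ± 1.72 (-0.08 ± 0.16), with edgeR adjusted p of 0.445, 0.701 and 0.788. RDR6 (AT3G49500), AGO1 (AT1G48410) and AGO2 (AT1G31280) had log2 fold changes of -0.30 ± 0.13, -0.15 ± 0.09 and -0.19 ± 0.14, none of them called. Of the 29 tested members of the list for post-transcriptional silencing and miRNA machinery, 4 rose and 1 fell (4 and 2 when adjusted over the list alone). The double-stranded RNA-binding genes DRB3 (AT3G26932, 1.04 ± 0.17, adjusted p = 0.00728) and HYL1 (AT1G09700, 0.72 ± 0.18, adjusted p = 0.0320), the nuclease gene SDN3 (AT5G67240, 0.89 ± 0.20) and the miRNA-processing gene TGH (AT5G23080, 0.66 ± 0.16) rose, and the Dicer gene DCL2 (AT3G03300) fell (-0.41 ± 0.11, adjusted p = 0.0409). The list was not called (camera, adjusted p = 0.503, and adjusted p = 0.874 with an estimated correlation). XRN2 (AT5G42540), an exoribonuclease gene, rose (0.75 ± 0.19) as the 1 called gene among 10 of RNA decay. The call of XRN2 was lost without any 1 library but fve-8 replicate 3. The calls of HYL1, SDN3, TGH and DCL2 were lost without WT replicate 1, 2 or 3 or without fve-8 replicate 2, and that of DRB3 without WT replicate 1 (adjusted p = 0.0529). DESeq2 did not call DCL2 (-0.39, adjusted p = 0.108), and the replicate block ended the calls of HYL1 (0.72, adjusted p = 0.0668) and DCL2 (-0.41, adjusted p = 0.0896). With library totals 11 members of the machinery list were called higher and 0 lower, SGS3 among them (0.52, adjusted p = 0.0381), and DCL2 was no longer called (-0.07).

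Precursors of trans-acting small interfering RNAs were not called, and 1 of their targets was. With edgeR, 0 of 5 tested TAS precursors were called, 0 had an unadjusted p under 0.05, and DESeq2, the likelihood-ratio test and limma-voom called 0. TAS3 (AT3G17185) had a log2 fold change of 0.40 ± 0.27, which rested on fve-8 replicate 3 at 24.9 CPM against 11.3 and 11.9 in the other fve-8 libraries. It was called higher with library totals (0.70, adjusted p = 0.0323). Without fve-8 replicate 3 TAS3 was -0.04, TAS1A went from 0.06 to -0.20 and TAS2 (AT2G39681) from 0.08 to -0.48. The list median went from 0.06 to -0.23 with 0 precursors called. That library held 2.07% of its counts on non-coding loci, a class that does not include these precursors, against 0.677% and 0.804% in the other fve-8 libraries. The remaining listed precursor, TAS4 (AT3G25795), was not tested. TAS1A (AT2G27400) had 9.48 ± 1.36 CPM in WT and 9.94 ± 3.12 in fve-8 (SD, n = 3). Of 12 tested targets of these RNAs 1 rose, PAP1 (AT1G56650), a call lost without WT replicate 1, WT replicate 2 or fve-8 replicate 2. Of 63 tested miRNA targets 2 fell, the laccase gene LAC4 (AT2G38080, -0.62 ± 0.13) and the auxin response factor gene ARF6 (AT1G30330, -0.49 ± 0.11). The miRNA target list was called lower (median log2 fold change -0.15, camera, adjusted p = 0.0157, and adjusted p = 0.247 with an estimated correlation), but with library totals its median was 0.19, below the 0.33 of all features, 6 targets were called higher and 0 lower, and its call was lost there (adjusted p = 0.118) and without fve-8 replicate 3 (adjusted p = 0.0678). Without WT replicate 1, WT replicate 3 or fve-8 replicate 2, 0 targets were called, without WT replicate 2, 1 lower, without fve-8 replicate 1, 1 higher and 6 lower, and without fve-8 replicate 3, 5 lower.

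The FLC group, downstream of FVE in flowering control, was not called. FLC (AT5G10140) had 5.51 ± 0.737 CPM in WT and 6.77 ± 0.995 in fve-8 (SD, n = 3; log2 fold change 0.30 ± 0.17, edgeR adjusted p = 0.264), and MAF2 (AT5G65050) and SVP (AT2G22540) had log2 fold changes of 0.34 ± 0.25 and -0.18 ± 0.13. With edgeR 0 of 5 tested members were called, 0 had an unadjusted p under 0.05, and DESeq2, the likelihood-ratio test and limma-voom called 0. LD (AT4G02560), another autonomous pathway gene, rose (0.77 ± 0.17, adjusted p = 0.0234), while FCA, FPA, FY, FLD, FLK and REF6 were not called. REF6 was called higher with library totals and without fve-8 replicate 3. The call of FVE was lost with library totals (-0.31, adjusted p = 0.178) and without WT replicate 1, 2 or 3 (adjusted p = 0.104, 0.0725 and 0.0618) or fve-8 replicate 2 (adjusted p = 0.0719). FLC was called higher with library totals (0.65, adjusted p = 0.0289). Without fve-8 replicate 3, MAF2 was called higher (0.60, adjusted p = 0.0133), as was MAF5 (AT5G65080), which did not pass the count filter with the full set of libraries, FLC stood at 0.43 (adjusted p = 0.0642), and the list median went from 0.08 to 0.31. Of 17 tested Polycomb and histone deacetylase or demethylase genes edgeR called 0, 1 had an unadjusted p under 0.05, and DESeq2, the likelihood-ratio test and limma-voom called 0, while library totals gave 2 called higher. Of the 7 tested Polycomb-silenced homeotic and embryo regulators 1 fell, the seed maturation regulator ABI3 (AT3G24650, -1.31 ± 0.31, adjusted p = 0.0268), and neither list was called by camera (adjusted p = 0.580 and 0.863). The call of LD was lost without WT replicate 1, WT replicate 2 or fve-8 replicate 2, and that of ABI3 without WT replicate 1, 2 or 3 or fve-8 replicate 1.

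**Figure D2:**
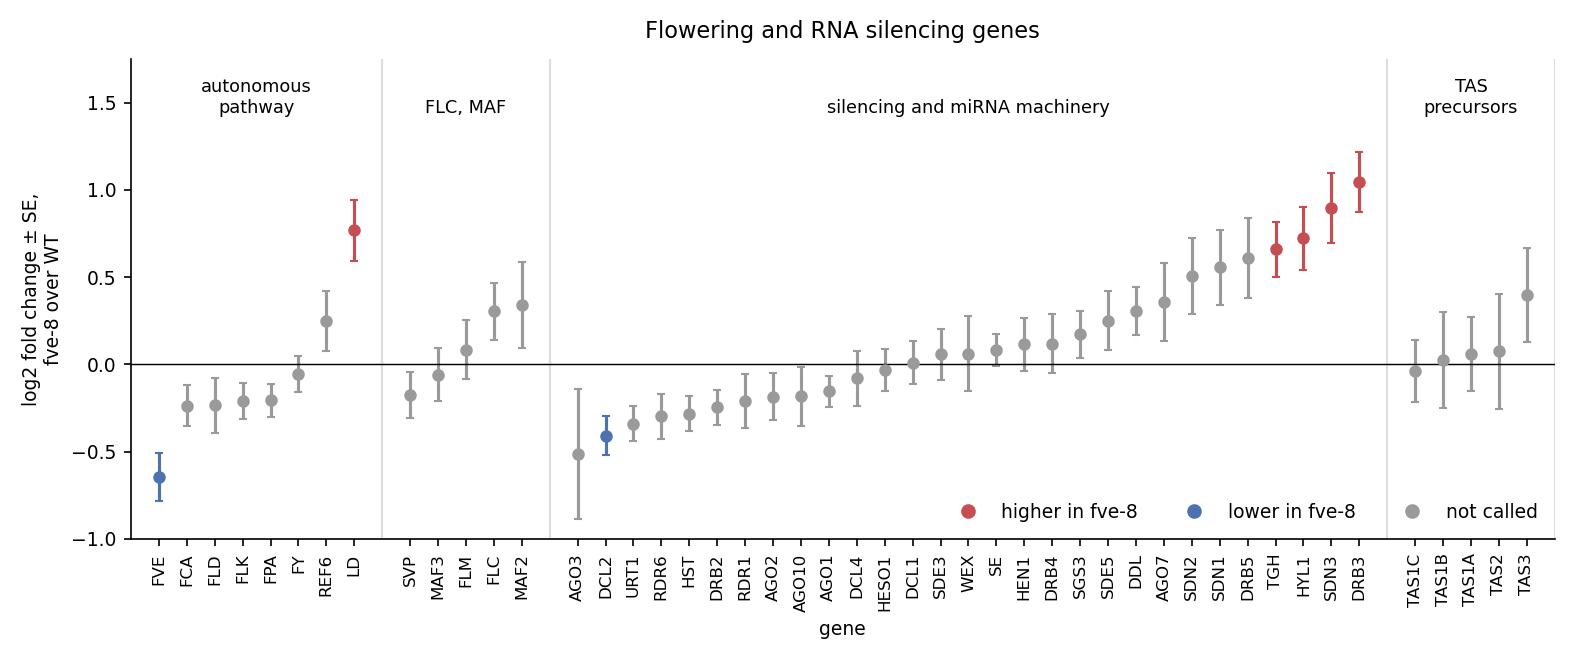
Log2 fold change of fve-8 over WT with its SE from edgeR (3 libraries per genotype) for each tested gene of the autonomous pathway, the FLC and MAF group, the silencing and miRNA machinery and the TAS precursors; red, called higher, blue, called lower, grey, not called. SGS3 at 0.17, DRB4 at 0.12 and DCL4 at -0.08 lie near 0, and DRB3 at 1.04 is the highest point.

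Of 8 tested seed storage and late embryogenesis markers 6 fell (6 when adjusted over the list alone): the globulin genes CRA1 (AT5G44120), from 43.7 ± 12.3 to 6.21 ± 1.96 CPM (SD, n = 3; log2 fold change -2.80 ± 0.26), and CRC (AT4G28520, -1.97 ± 0.36), the oleosin genes OLEO1 (AT4G25140, -2.56 ± 0.22) and OLEO2 (AT5G40420, -2.44 ± 0.18) among them. The other 2 tested members were not called, and without WT replicate 2 the members called lower numbered 3. The list was called lower (camera, adjusted p = 3.5e-06, and adjusted p = 0.295 with an estimated correlation). Outside the list, the seed tonoplast aquaporin gene TIP3;1 (AT1G73190, -2.73 ± 0.18), the beta-glucosidase gene BGLU19 (AT3G21370, -2.53 ± 0.20), AT3G21380 (-2.42 ± 0.25) and AT2G25890 (-2.11 ± 0.19) were among the 12 largest falls. Of 12 tested root markers 3 fell, TIP2;3 (AT5G47450, -1.20 ± 0.19), CASP1 (AT2G36100, -0.71 ± 0.10) and COBL9 (AT5G49270, -0.68 ± 0.16), and the list was called lower (median -0.30, camera, adjusted p = 0.00841, and adjusted p = 0.247 with an estimated correlation), although its median was 0.03 with library totals, below the 0.33 of all features. Under that scaling 1 root marker was called higher and 1 lower.

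Of 15 tested cold-response genes 5 fell, and of 20 tested photosynthesis genes 2 fell. The 3 CBF genes, transcription factors of the cold response, fell together: CBF2 (AT4G25470) from 25.1 ± 5.80 to 9.96 ± 1.82 CPM (SD, n = 3, -1.34 ± 0.19), CBF1 (AT4G25490, -1.19 ± 0.25) and CBF3 (AT4G25480, -1.08 ± 0.25). The cold and drought marker RD29A (AT5G52310, -2.03 ± 0.46) also fell, from 44.6 ± 28.6 CPM, a wide spread between the WT libraries. The cold list was called lower (6 members when adjusted over the list alone, with camera, adjusted p = 0.000401, and adjusted p = 0.366 with an estimated correlation). Without WT replicate 1, WT replicate 2 or fve-8 replicate 2, 2, 1 and 2 members were called lower. Of the photosynthesis genes LHCB1.4 (AT2G34430, -0.82 ± 0.14) and LHCB1.1 (AT1G29920, -0.46 ± 0.13) fell, beside the lower plastid share of the same libraries. That list was called lower (median -0.19, camera, adjusted p = 0.00462, and adjusted p = 0.527 with an estimated correlation), with a median of 0.14 under library totals, below the 0.33 of all features, and the call was lost without fve-8 replicate 1 (adjusted p = 0.104). Without WT replicate 2, 0 of its genes were called lower, and without fve-8 replicate 3, 7. Clock genes went both ways. The morning genes LHY (AT1G01060, 1.57 ± 0.42, with overlapping genotypes) and CCA1 (AT2G46830, 1.33 ± 0.33) rose, the evening genes GI (AT1G22770, -0.75 ± 0.17) and TOC1 (AT5G61380, -0.65 ± 0.13) fell, 10 of 14 tested members were not called, and the list was not called (camera, adjusted p = 0.489). Without WT replicate 1, WT replicate 2 or fve-8 replicate 2, 0 clock genes were called, without WT replicate 3, 0 higher and 1 lower, and with library totals 3 higher and 0 lower. Without fve-8 replicate 1 there were 3 higher and 4 lower, and without fve-8 replicate 3, 2 higher and 4 lower.

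Members of the jasmonate, glucosinolate, iron-deficiency, flavonoid and heat shock lists were called higher, each in part. Of 4 tested jasmonate-response genes 3 rose (4 when adjusted over the list alone): the lipoxygenase gene LOX2 (AT3G45140) from 178 ± 2.80 to 354 ± 77.1 CPM (SD, n = 3, 0.99 ± 0.15), VSP1 (AT5G24780, 1.68 ± 0.22) and VSP2 (AT5G24770, 2.01 ± 0.44). The list had a camera adjusted p of 0.000401 and an adjusted p = 0.213 with an estimated correlation. Of 18 tested glucosinolate genes 8 rose and 1 fell (13 and 1 when adjusted over the list alone), among them CYP79F1 (AT1G16410, 1.49 ± 0.24) and CYP79F2 (AT1G16400, 1.03 ± 0.23) of the aliphatic branch, whose near-identical sequences may share reads, and BCAT4 (AT3G19710, 0.85 ± 0.13). This list had a camera adjusted p of 3.5e-06 and an adjusted p = 0.213 with an estimated correlation. Of 9 tested iron-deficiency genes 5 rose (6 when adjusted over the list alone): the ferric reductase gene FRO2 (AT1G01580) from 25.3 ± 1.06 to 54.1 ± 7.27 CPM, and the transcription factor genes BHLH38, BHLH39 and BHLH100 (AT2G41240, 2.42 ± 0.27) among them. This list had a camera adjusted p of 3.1e-05 and an adjusted p = 0.213 with an estimated correlation. Of 9 tested flavonoid genes 4 rose (4 when adjusted over the list alone), PAP1 (2.03 ± 0.39), LDOX (1.68 ± 0.41), DFR (1.43 ± 0.37) and CHS (0.96 ± 0.26, with overlapping genotypes), with a camera adjusted p of 0.00245 and an adjusted p = 0.247 with an estimated correlation. Limma-voom called 1 of them. Of 7 tested heat shock genes 3 rose (5 when adjusted over the list alone), HSP17.6II (AT5G12020, 3.27 ± 0.56), HSP17.4 (AT3G46230, 1.83 ± 0.49) and HSP90.1 (AT5G52640, from 5.13 ± 1.03 to 13.5 ± 5.77 CPM), with a camera adjusted p of 0.00153 and an adjusted p = 0.348 with an estimated correlation. Without WT replicate 1, 2 or 3 or fve-8 replicate 2, the flavonoid genes called higher numbered 0, 0, 1 and 0, the heat shock genes 0, 0, 2 and 1, the glucosinolate genes 1, 3, 4 and 5, and the iron-deficiency genes 5 each time. In the same order of lists they numbered 5, 6, 8 and 5 without fve-8 replicate 1, and 4, 3, 11 and 5 without fve-8 replicate 3. Library totals gave 8, 5, 15 and 7 higher, and 0 glucosinolate genes lower. The heat shock median was 1.04, and 1.55 or 0.67 without fve-8 replicate 1 or 2. Of 6 tested salicylic acid defence genes edgeR and DESeq2 called 0, 1 had an unadjusted p under 0.05, the likelihood-ratio test called 1 and limma-voom 0. With library totals 2 of them were called higher, and without fve-8 replicate 3, 1.

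Auxin-responsive genes went both ways. The amido synthetase genes GH3.2 (AT4G37390, -1.35 ± 0.12), GH3.5 (AT4G27260) from 121 ± 6.40 to 61.9 ± 2.75 CPM (SD, n = 3, -0.97 ± 0.09) and GH3.3 (AT2G23170, -0.88 ± 0.14) fell, and the auxin-induced repressor gene IAA2 (AT3G23030, 1.16 ± 0.25) rose. In all 2 of 9 tested members rose and 4 fell (2 and 4 when adjusted over the list alone, with camera, adjusted p = 0.0498, and adjusted p = 0.295 with an estimated correlation). Members called higher numbered 0 without WT replicate 1, WT replicate 2 or fve-8 replicate 2, and 1 without WT replicate 3 or fve-8 replicate 1. That list's call was lost without WT replicate 2, WT replicate 3, fve-8 replicate 2 or fve-8 replicate 3, with adjusted p between 0.0534 and 0.118. Among the single genes with the largest rises were AIG1 (AT1G33960), a gene known from pathogen responses, 17.1-fold higher (adjusted p = 0.00149), TSA1 (AT1G52410, 3.13 ± 0.32), the myrosinase-binding protein genes MBP1 (AT1G52040, 2.46 ± 0.30) and MBP2 (AT1G52030, 2.47 ± 0.33), TAT3 (AT2G24850, 2.43 ± 0.40) and GH9B15 (AT4G23560, 2.34 ± 0.35).

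**Figure D3:**
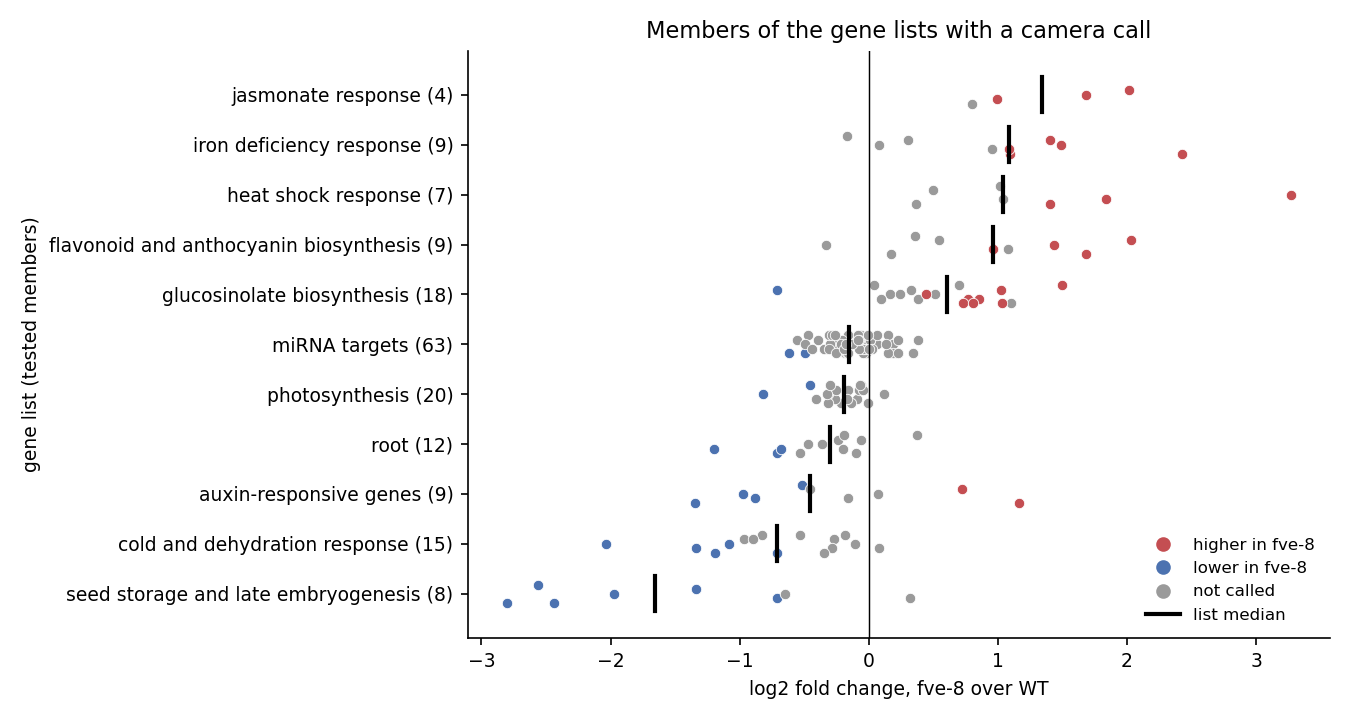
Log2 fold change of fve-8 over WT for each tested member (points; number in brackets) of the 11 gene lists called by camera, with the list median as a bar; red, called higher, blue, called lower, grey, not called. Medians run from -1.65 for the seed list to 1.34 for the jasmonate list. With library totals the medians of the root, photosynthesis and miRNA target lists were above 0.

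**Figure D4:**
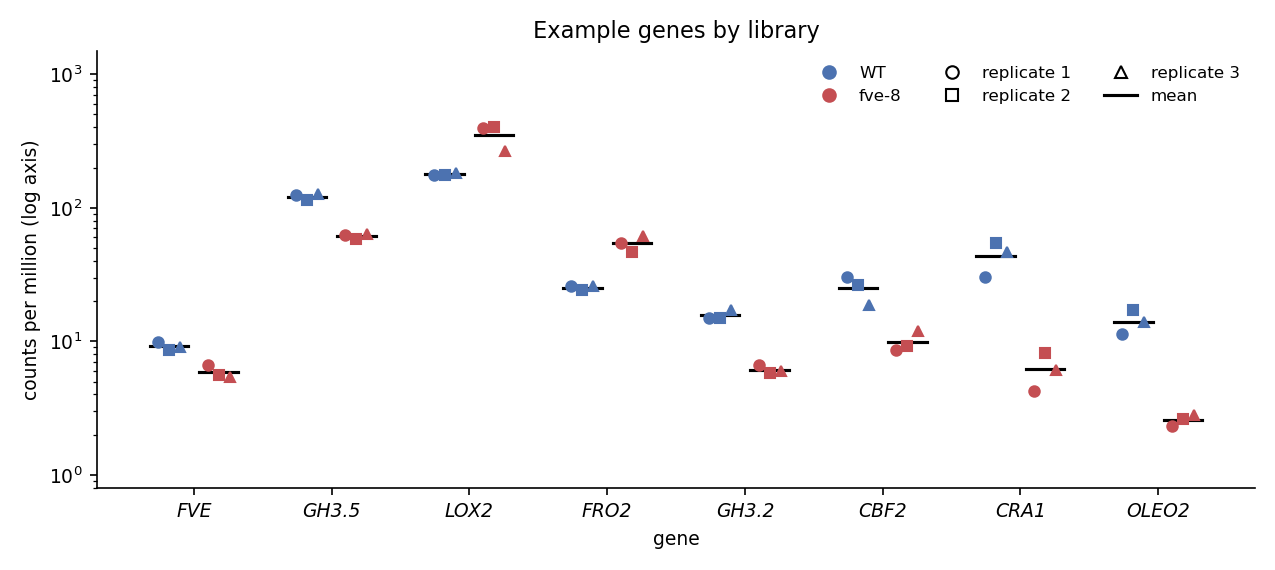
CPM on a log axis for 8 genes in each of the 3 WT (blue) and 3 fve-8 (red) libraries, with the genotype mean as a line. CRA1 went from a mean of 43.7 to 6.21 and LOX2 from 178 to 354, and the libraries of the genotypes do not overlap for any of the 8 genes.

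The second comparison asked which mature miRNA entries differed between fve-8 and WT. The deposited table names entries by identifier only and the files do not pair these with miRNA names, so no family is named. Of 271 tested entries 21 were higher and 6 lower in fve-8 (edgeR, adjusted p under 0.05), with rises of 1.93-fold to 15.8-fold and falls of 1.41-fold to 2.04-fold. These changes are relative to the miRNA counts of each library, whose totals were smaller in both fve-8 libraries. MIMAT0000939, which stood for a set of 6 entries with near-identical counts, went from 42.6 ± 5.59 CPM in WT (SD, n = 2) to 674 ± 157 in fve-8 (n = 2), a log2 fold change of 3.98 ± 0.33. MIMAT0022400 went from 28.2 ± 8.71 to 316 ± 61.5 CPM (3.49 ± 0.41). MIMAT0031898, whose counts nearly match those of another entry, fell from 901 ± 4.86 to 443 ± 63.8 CPM (-1.03 ± 0.23), and MIMAT0020532 fell from 4344 ± 846 to 2266 ± 438 (-0.94 ± 0.19). Entries with near-identical counts may share reads, so the calls may represent fewer independent RNAs. The 21 higher entries fell into 12 sets of near-identical counts and the 6 lower into 4. Leaving out fve-8 replicate 1 left 9 entries higher, leaving out fve-8 replicate 2 gave 35, and without WT replicate 1 or WT replicate 2 the lower entries numbered 1 and 0. The authors' deposited table lists 21 entries higher and 8 lower at an adjusted p under 0.05, and 15 of the 21 higher and 4 of the 6 lower entries called here were called with the same sign in the authors' deposited table. MIMAT0020532 has an adjusted p of 0.593 in the authors' deposited table.

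**Figure D5:**
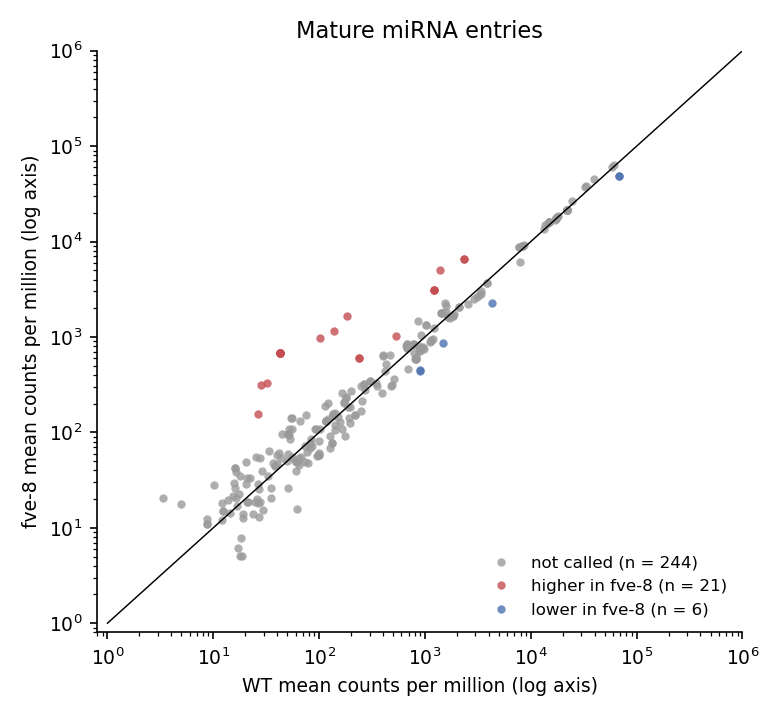
Mean CPM of each of the 271 tested mature miRNA entries in WT (horizontal, 2 libraries) and fve-8 (vertical, 2 libraries), both on log axes with the line of equality; red, 21 entries called higher, blue, 6 called lower, grey, 244 not called. The entries called higher include several between 20 and 200 CPM in WT that lie well above the line.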

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

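Of the alternatives, leaving out organelle genes, collapsing near-identical small RNA entries and thinning the small RNA libraries were chosen after seeing the data. The cause of each shift below was not tested, except where fewer samples or a stricter threshold set it by construction. With library totals only, 5440 genes were higher and 181 lower, and 123 elements higher. An absolute log2 fold change of at least 1 left 364 genes higher and 116 lower, and 2 small RNAs lower. With no low-count filter 146 elements were higher and 14 lower, and with a mean of at least 1 CPM 53 were higher. Leaving out 1 library at a time, genes higher ranged from 1.7e+02 (without WT replicate 1) to 2311 (without fve-8 replicate 3) and genes lower from 125 to 1952, elements higher from 48 to 121 and lower from 2 to 14, small RNAs higher from 9 (without fve-8 replicate 1) to 35 and lower from 0 to 4. Without fve-8 replicate 3, 2162 of the 2176 called genes were called again, and without WT replicate 1, 291. Where 1 small RNA library of a genotype is left, it is assumed to vary like the pair of the other genotype. RLE scaling, DESeq2, the likelihood-ratio test and limma-voom kept each count of genes, elements and small RNAs within 1.5 times, and leaving out organelle genes did so for genes and elements. Camera called 11 of 23 lists with a preset correlation, 0 with an estimated correlation and 8 with fry. Over all alternatives, results for single named genes kept their side of the threshold 1656 times, lost a call in 8.93% of fits and gained one in 0.925%, and 0 were called in the opposite direction. These shares are over the fits of all named genes, including those with no call to lose or to gain. Of 83 called named genes, 37 lost the call without WT replicate 1, 38 without WT replicate 2, 30 without fve-8 replicate 2 and 10 with library totals. At this depth 22.4% of simulated 1.5-fold RNA changes and 7.14% of such small RNA changes were recovered, so a gene not called may still differ.

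With the replicate number as a replicate block, 683 genes were higher and 449 lower, 76 elements were higher and 9 lower, 22 small RNAs were higher and 5 lower, and 10 lists were called. The numbers did not pair the samples: residuals of libraries with the same number correlated at -0.01, -0.06 and -0.15 in RNA and -0.06 in small RNA.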

Other observations

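The family screen and the lower-bound folds were chosen after the results were seen. A ratio of tested elements to genes under the count filter and a test on 4 seed genes, also chosen then, were dropped because the choice of members shaped their outcome. A screen of 101 families of genes that share a symbol stem called 3 families with camera: bHLH factors higher, and plasma membrane aquaporins (PIP) and 3-ketoacyl-CoA synthases (KCS) lower. Of 11 tested PIP genes 3 fell, PIP2;4 (AT5G60660; log2 fold change -1.14 ± 0.16), PIP1;5 (AT4G23400; -0.46 ± 0.09) and PIP1A (AT3G61430; -0.36 ± 0.09), with a median of -0.30 that was 0.02 with library totals, against 0.33 for all features there (camera, adjusted p = 0.00970; adjusted p = 0.856 with an estimated correlation). Of 17 tested KCS genes, which elongate very-long-chain fatty acids for waxes, 5 fell, among them KCS6 (AT1G68530; -0.56 ± 0.12) and KCS1 (AT1G01120; -0.54 ± 0.12), with a median of -0.26 that was 0.07 with library totals (camera, adjusted p = 0.0254; adjusted p = 0.856 with an estimated correlation). The 5 of 12 bHLH genes that rose include BHLH38, BHLH39 and BHLH100, which are also members of the iron-deficiency list. The others were bHLH115 (AT1G51070, 0.60 ± 0.11) and bHLH071 (AT5G46690, 0.89 ± 0.19). This family had a median of 0.46, a camera adjusted p of 0.00391 and an adjusted p = 0.777 with an estimated correlation.

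For the rise of transposable elements in fve-8, a lower organelle share would raise nuclear features alike, but the elements' median log2 fold change of 0.23, the same with elements at 0 in WT set to their lower bound, lay above 100% of 10000 lists of nuclear genes matched on mean CPM, whose central 95% ran from -0.04 to 0.08. Genomic DNA in the fve-8 libraries would add counts to silent genes as well, and the values it needs were present, since the summed CPM of 9546 nuclear genes under the count filter rose from 730 ± 25.6 to 807 ± 43.9 (SD, n = 3), 1.105-fold, with the 3 fve-8 libraries above the 3 WT libraries. Elements under the count filter rose in sum from 121 ± 11.3 to 178 ± 6.16 CPM, and elements with counts went from 1098 to 1240 per WT library to 1459 to 1557 per fve-8 library. Of 31189 elements 29311 had 0 counts in the 3 WT libraries and 28787 in the 3 fve-8 libraries. Among fve-8 libraries, however, replicate 3 had the highest sum of nuclear genes under the count filter (857, against 774 and 790 CPM). It also had the lowest sum of tested elements (1151, against 1344 and 1290). Elements under the count filter did not share this drop, with 181.9 CPM in replicate 3 against 182.1 and 171.4 in replicates 1 and 2. DNA stays open as a part of the rise. The 10 splits of the 6 libraries are too few for a share under 0.05: the real split called 80 elements one way and the other splits at most 0 with edgeR, where at most 31 elements had an unadjusted p under 0.05, and 1 split in all gave as many. A release of elements from silencing in fve-8 also stays open as a hypothesis, as do transcripts running from neighbouring genes into elements, which were not tested without element positions.

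Seed storage transcripts were lower in fve-8. The seed list's median of -1.65 lay above 0% of 10000 matched lists. A lower organelle share would raise nuclear genes alike, so by its direction it could not lower this list. The matched lists therefore add no test of it. One smaller share of seed-derived RNA would lower the members by the same factor if all their RNA came from the seed. The log2 fold changes of the 8 tested members, from -2.80 to 0.32, differed by more than their errors (heterogeneity chi-square 101 on 7 degrees of freedom). This argues against a smaller seed share as the only cause for the whole list. Members also expressed in the seedling would differ in the same way, so the test cannot decide on a smaller seed share for the others. A smaller seed share behind part of the members, with expression in the seedling behind the others, stays open. The dropped test found 4 storage protein and oleosin genes alike within their errors (heterogeneity chi-square 3.77 on 3 degrees of freedom, p = 0.288). It cannot decide this, because the choice of its members shaped its outcome. Whether the seedlings of the genotypes differed in age since germination was not tested, and a change of seed gene expression in fve-8, with ABI3 also lower, stays open.

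Called genes showed no detectable excess among the 200 tested genes nearest to FVE. Variants in the mutant line linked to FVE could act on the genes beside them. Genes near FVE would then be called more often. Of the 200 tested genes nearest to FVE in gene order 26 were called (13.0%), against 11.2% of 18749 other nuclear genes (Fisher's exact test, two-sided p = 0.429). These 200 genes are too few to hold most of the 2176 called genes, so the test covers only a local excess. A linked variant acting on genes elsewhere would leave no such excess, so the test cannot decide on it. The 10 splits of the 6 libraries are too few for a share under 0.05: the real split called 2176 genes and the other splits at most 0 with edgeR, where at most 1805 genes had an unadjusted p under 0.05, and 1 split in all gave as many. The split with 1805 put fve-8 replicate 3 with WT replicates 1 and 2.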
